A study of Mus musculus with 11 samples.

How the data were processed

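RNA abundance was measured on 11 Illumina MouseWG-6 bead arrays, each read once for 1 sample of mouse embryonic stem cells or of embryoid bodies harvested on day 6 of differentiation. A bead array reports the brightness of labelled cRNA bound to beads that carry 1 probe sequence each, so the values are intensities and not read counts. The number of arrays, not a sequencing depth, limits the precision. The cells came from a male C57BL/6 line in which the genes of connexin43 and connexin45 were either flanked by recombination sites, called the control line here, or lacked exon 3 of both genes, called the deleted line here. Per the labels, the deleted line also carries reporter genes driven by the promoters of both connexins, so the lines differ in more than the loss of the proteins.

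The deposited intensity of each probe on each array is not normalized between arrays. Per the labels and the series' design text, the authors made it with GenomeStudio 2011.1 and its Gene Expression module 1.9.0, and afterwards quantile normalized the raw intensities. The submitters' processing notes name limma. Whether a background was subtracted before export is not given in the sources used here. The lowest deposited intensity is 85.9, above 0, so values were taken to the log2 scale without an offset. Beside each intensity the authors deposited a detection p-value, which ranks the probe against the negative control beads of the same array and moves in steps of 1 in 936. All 22 columns matched 1 sample title each, 2 per sample. No source used here pairs the array's probe identifiers with genes, so no gene is named, and gene lists fixed before the data were examined, the 2 deleted genes and the count with 1 probe per gene were not analysed here. Genomic positions of the probes were not used here either.

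Intensities were quantile normalized over the 11 arrays and log2 transformed. Of 45281 probes, 23268 had a detection p-value under 0.05 on at least 2 arrays and were kept. The remaining 22013 were left out of the tests. A model with 4 group means was fitted to all 11 arrays with limma 3.58.1 in R 4.3.3, with default empirical Bayes moderation, because the stem cell groups hold 2 arrays each and need the shared estimate of spread. Benjamini-Hochberg adjustment ran over the 23268 probes within each of 5 comparisons, and the threshold was an adjusted p of 0.05. The comparisons were deleted against control embryoid bodies, deleted against control stem cells, embryoid bodies against stem cells in each line, and the interaction, which is the genotype difference in embryoid bodies minus that in stem cells. Because the deposited intensities still hold the array background of about 102.5 to 121.2 units, fold changes of dim probes are compressed towards 1. Standard errors are limma's moderated ones.

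Up to 2 probes with the largest fold change in each direction are named per comparison, among probes past the threshold whose arrays in the 2 groups did not overlap. For the interaction, only the threshold applied. This rule, the tests and the alternatives were fixed before the data were examined. The measures of stage position, stage ratio and detection class, the simulated mixtures of control groups and the comparisons of single stem cell arrays were added after seeing the data. Position places an array between control stem cells, at 0%, and control embryoid bodies, at 100%, as the slope of its log2 difference from control stem cells on the control line's stage change, over probes that changed at least 2-fold. A control array was placed against the other control arrays only. The stage ratio divides the mean change of the deleted line by that of the control line, in probes chosen on 1 control stem cell and 1 control embryoid body array and measured in the control arrays not used for the choice. A probe counted as detected in 1 group only when its detection p-value was under 0.01 on every array of that group and at least 0.05 on every array of the other.

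Alternatives were median scaling, limma's neqc background correction with an offset of 16, no detection filter, a stricter filter at 0.01 on at least 3 arrays, a fit of the compared groups alone, the replicate number as a block, limma's trended robust moderation, and each array left out in turn. Estimated array weights were added after seeing the data. The fit was tested on simulated data drawn from the real group means and spreads, with 200 of 23268 probes changed. For embryoid bodies it recovered 96% of changes of 1 on the log2 scale and 22% of changes of 0.5. For stem cells it recovered 60% and 12%, and 100% of changes of 2 in both comparisons. The changed probes were drawn only from brighter ones, above a fixed group mean, so recovery of dim probes near background was not tested. Larger changes were planted beside the smaller ones, which eases the adjusted threshold for these. Recovery in real data with few or no calls may therefore be lower. No 2 arrays shared the same deposited intensity at more than 2 probes.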

Results

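Gene expression was profiled in mouse embryonic stem cells and in embryoid bodies, the aggregates that such cells form when they differentiate in hanging drops. One line lacked connexin43 and connexin45, channel proteins of the gap junctions that couple neighbouring cells. The control line carried both genes with recombination sites around them. The series title names primitive endoderm, the outer epithelium of early embryoid bodies, as the tissue of interest. There were 2 arrays of control stem cells, 2 of deleted stem cells, 3 of control embryoid bodies and 4 of deleted embryoid bodies, the last 2 groups at day 6 and each from a pool of about 300 bodies. The submitters call them biological replicates, but no label ties an array to a culture, so p-values measure the spread between these samples. Each genotype is represented by a single described line, so the p-values do not measure the spread between lines. A genotype difference below therefore means a difference between these 2 lines. The deleted genes themselves were not analysed here, because probes were not matched to genes, so the labels have no check of that kind. Probes are therefore described by identifier and by group.

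Each array measured 45281 probes. Between 39.7% and 43.0% of them were detected per array, and mean intensity ranged from 381 to 503 units. After quantile normalization, arrays of the same group correlated across probes at r of 0.969 to 0.993. Control and deleted embryoid bodies correlated less, at 0.927 to 0.946. The first principal component, with 51.1% of the variance, ran from stem cells to embryoid bodies, and deleted embryoid bodies lay between the other groups on it. The second, with 25.7%, put the 4 deleted embryoid body arrays between -40.1 and -27.8 and all other arrays between 8.54 and 35.3. Array background was lower in deleted than in control embryoid bodies, at 104.7 ± 2.06 units (SD, n = 4) against 109.0 ± 1.09 (SD, n = 3), with no overlap between the arrays.

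Deleted embryoid bodies were compared with control embryoid bodies to ask which transcripts differ between the lines at day 6. Of 23268 probes tested, 5246 passed the threshold, 2552 higher and 2694 lower in deleted bodies, a balance that turned to 2380 higher and 1980 lower under median scaling. Changes of at least 2-fold numbered 529 upward and 595 downward. The lowest was ILMN_1225816, which fell from a normalized intensity of 20367 ± 13680 (SD, n = 3) in control bodies to 115.5 ± 6.71 (SD, n = 4) in deleted bodies, where it was detected on 0 of 4 arrays. Its log2 fold change was -7.08 ± 0.51 (SE, limma adjusted p = 1.4e-05), a fitted difference of 135-fold whose size is limited by background, the level of the deleted bodies. The control arrays of this probe were uneven, at 30517, 25774 and 4811 units, and without replicate 3 the log2 fold change was -7.93. ILMN_1256343 fell 96.1-fold in the fit, a size also limited by background, from 15966 ± 2401 to 170.7 ± 56.0 units. Its log2 fold change was -6.59 ± 0.21 (SE, limma adjusted p = 1.6e-07). Upward, ILMN_2645460 was 12.6-fold higher, at 5497 ± 835 against 482 ± 246 units (log2 fold change 3.65 ± 0.37 SE, limma adjusted p = 0.00012). ILMN_1249766 was 11.7-fold higher in the fit, a size limited by background, at 1834 ± 303 against 158 ± 37.4 units, with detection on 2 of 3 control arrays (log2 fold change 3.55 ± 0.18 SE, limma adjusted p = 2.0e-06).

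**Figure D1:**
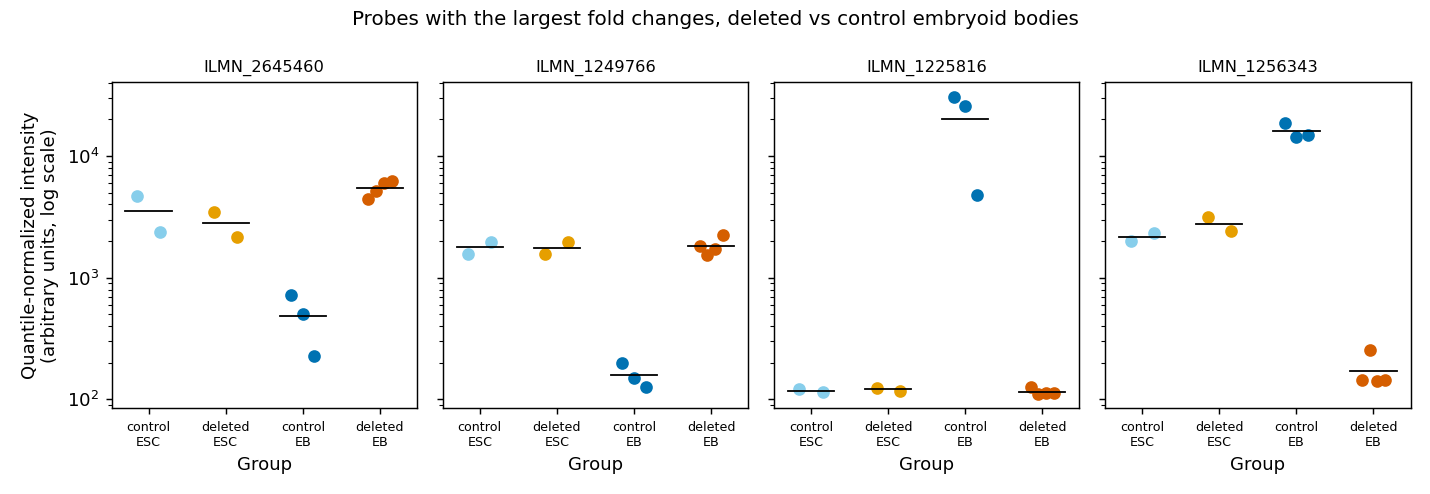
Quantile-normalized intensity (arbitrary units, log scale) of the 4 probes with the largest fold changes between deleted and control embryoid bodies, in each group; points are arrays and lines are group means. ILMN_1249766 averaged 1834 units in deleted embryoid bodies and 1779 and 1756 in control and deleted stem cells, while ILMN_1225816 was detected on 0 arrays outside the control embryoid bodies.

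Some transcripts differed in detection itself. A set of 167 probes was detected on all 3 control embryoid body arrays and on none of the 4 deleted ones. Of these, 98 were also undetected on all 4 stem cell arrays, and 12 were detected on all of them. The opposite set held 161 probes, of which 66 were detected on all 4 stem cell arrays and 28 on none. Among the 35 ways to split the 7 embryoid body arrays into 3 and 4, the real one gave the highest count for both sets, and the highest other counts were 23 and 14. Every other split mixes arrays of both lines, which lowers its counts if the lines differ. The measure was also chosen after seeing the data, so this ranking describes the separation and is not an independent test of it.

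Embryoid bodies were then compared with stem cells within each line, which describes differentiation with and without the 2 connexins. In the control line 8789 probes passed the threshold, 4264 rising and 4525 falling (3880 and 3372 under median scaling), with 1461 and 1319 of them by at least 2-fold. ILMN_1225816 rose 132-fold in the fit (log2 fold change 7.05 ± 0.61 SE, limma adjusted p = 3.5e-05), a size limited by background because it was detected on 0 of 2 control stem cell arrays, and ILMN_2708477 rose 112-fold, from 254 ± 65.8 units (SD, n = 2) to 28107 ± 2628 (SD, n = 3). ILMN_2860932 fell 35.3-fold, from 14402 ± 10283 (SD, n = 2) to 357 ± 69.6 units (SD, n = 3). Its log2 change was -5.14, and -4.34 without control stem cell replicate 1 or -5.94 without replicate 2. ILMN_2960700 fell 25.4-fold, from 16085 to 632 units. In the deleted line 5189 probes passed, 2440 rising and 2749 falling (2224 and 1929 under median scaling), with 511 and 657 by at least 2-fold. ILMN_2708477 rose 7.98-fold, to 1703 ± 564 units (SD, n = 4), and ILMN_2670625 rose 7.86-fold. ILMN_2693895 fell 88.7-fold in the deleted line, to 229 ± 62.6 units, and ILMN_2923445 fell 46.4-fold in the fit, to 130.9 ± 13.0 units, close to background, with detection on 3 of 4 arrays. In the control line ILMN_2693895 ranged from 1102 to 11654 units on the embryoid body arrays, and its stage change of -1.86 ± 0.75 (SE) on the log2 scale did not pass (limma adjusted p = 0.076). The labels give no array run, so a run difference between the stages was not tested. A shift shared by both lines would move a detected probe alike in both. ILMN_1256343 instead rose in the control line and fell in the deleted line, and its interaction passed. That probe was named for its large change, so it does not speak for the other probes. ILMN_1225816, undetected on every array of the deleted line, cannot show such a shift. Without control stem cell replicate 1 the control line's count was 5232, and without deleted stem cell replicate 2 the deleted line's count was 2627.

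Of the 4264 probes that rose in the control line, 1285 also rose in the deleted line, 147 fell and 2832 did not pass. Of the 4525 that fell, 1695 also fell, 101 rose and 2729 did not pass. Independent lists of these sizes would share 447 rising and 535 falling probes. These 2 stage comparisons share no arrays, and across probes, which are not independent replicates, their fold changes correlated at Pearson r = 0.55 and Spearman rho = 0.52. In probes chosen on 1 pair of control arrays and measured on the rest, the control line changed by 1.14 to 1.49 and the deleted line by 0.48 to 0.69 on the log2 scale over the 6 possible choices. The ratio of deleted to control change averaged 0.430, with a range of 0.397 to 0.464. It was 0.349 for rising and 0.525 for falling probes. Deleted stem cells already lay at a position of 22.2% ± 17.0 (SD, n = 2) on rising and 10.1% ± 8.09 on falling probes. The gap between these 2 ratios therefore does not describe the embryoid bodies alone. The size of the ratio over all chosen probes rested on the deleted stem cell arrays, being 0.544 without replicate 1 and 0.315 without replicate 2.

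**Figure D2:**
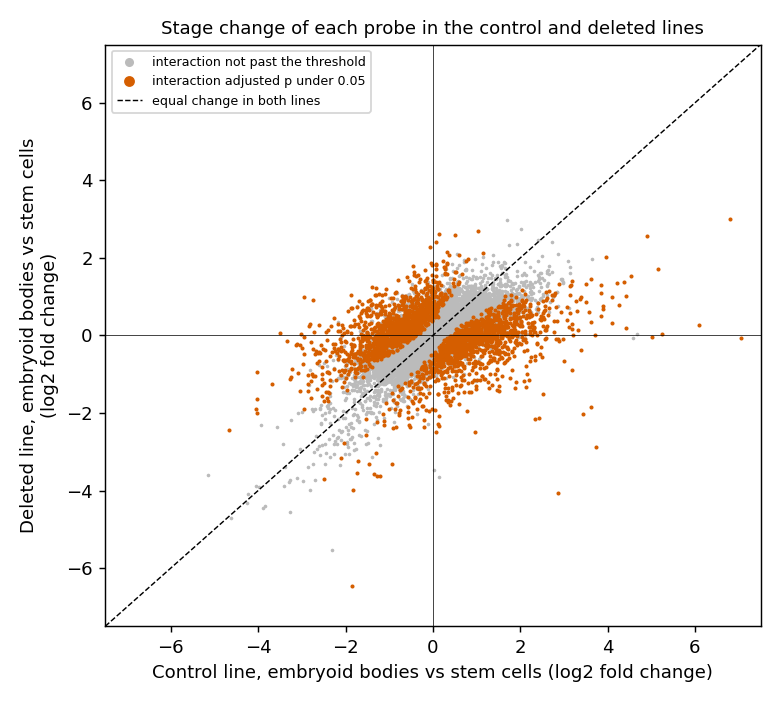
Log2 fold change from stem cells to embryoid bodies for each of the 23268 probes, in the control line (x axis) and the deleted line (y axis); orange points are the 2693 probes past the threshold for the interaction and the dashed line marks equal change. Across probes the 2 changes correlated at r = 0.55.

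On the axis from control stem cells to control embryoid bodies, the deleted embryoid bodies lay at 56.0% ± 3.66 (SD, n = 4) and the control embryoid bodies, each placed against the other control arrays, at 94.7% ± 5.26 (SD, n = 3). The 4 deleted arrays spanned 50.8% to 59.0% and the 3 control arrays 91.0% to 100.7%. With the positions held fixed, the difference of -38.7 points had a two-sided permutation p of 0.029, the smallest that 35 splits allow. The axis rests on the control labels and was not rebuilt for each split, and the measure was chosen after seeing the data. This p therefore describes the separation and is not an independent test of it. On rising probes alone the deleted bodies stood at 51.3% ± 3.31 (SD, n = 4), and on falling probes at 61.8% ± 4.13, higher in 4 of 4 arrays.

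**Figure D3:**
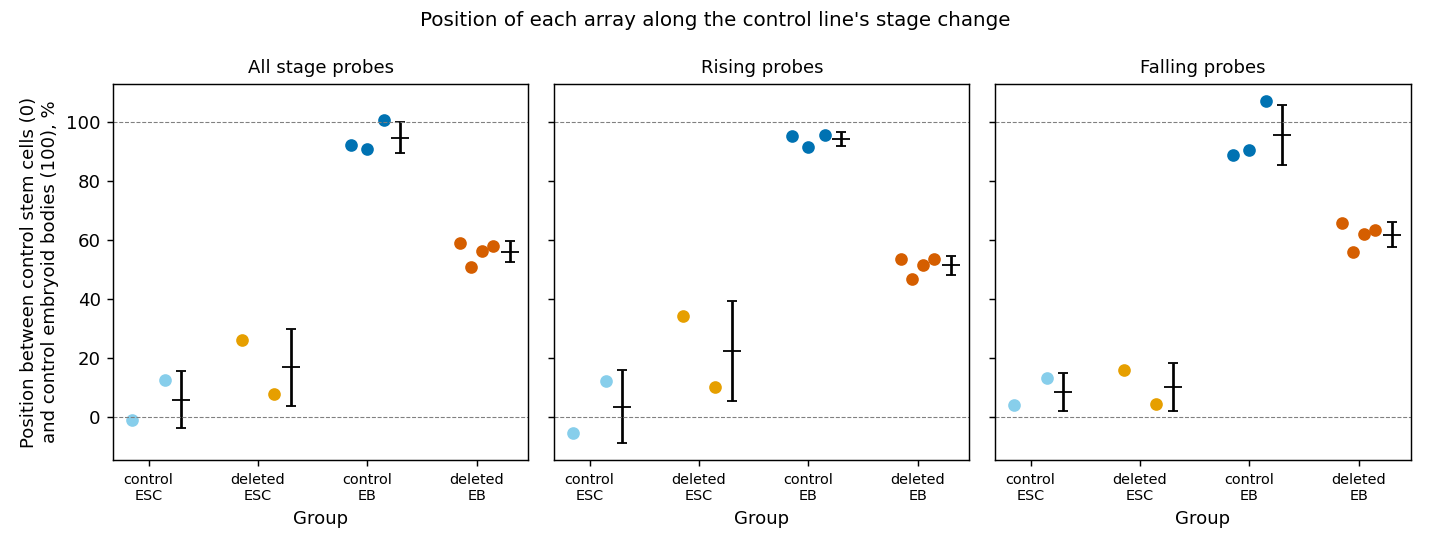
Position of each array (points) between control stem cells (0%) and control embryoid bodies (100%), from all probes that changed at least 2-fold between them, from the rising ones and from the falling ones; the mark and bar beside each group are its mean and SD. Deleted embryoid bodies lay at 50.8% to 59.0% over all such probes, and deleted stem cell replicate 1 at 26.0%.

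The genotype difference in embryoid bodies was also set against the control line's stage change. Of the 4264 rising probes, 1689 were lower in deleted than in control bodies and 121 higher. Of the 4525 falling probes, 1324 were higher and 114 lower. A further 1998 of the 5246 genotype calls, 1107 higher and 891 lower, had no stage call in the control line. Both comparisons use the control embryoid body arrays, which alone makes them negatively correlated. Across probes the observed r was -0.58 and the covariance -0.200. In a simulation every array was redrawn from its group mean, with deleted bodies set equal to control bodies and noise independent between probes. Over 20 draws it gave r = -0.11, a covariance of -0.012 and 0 genotype calls on average. Deviations that an array shares across probes were not simulated, so shared arrays alone may give a stronger correlation than this. Independent lists would share 494 lower-and-rising and 496 higher-and-falling probes. The 3 control arrays could not be divided into sets of at least 2, so part of the excess may come from the shared arrays.

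The interaction asked whether the genotype difference itself differed between stages. It passed for 2693 probes, 1306 with a more positive and 1387 with a more negative difference in embryoid bodies. ILMN_1225816 had an interaction of -7.11 ± 0.84 (SE, limma adjusted p = 0.00097) on the log2 scale. Its size is limited by background, because the probe was undetected in every group but control embryoid bodies. ILMN_1256343 had an interaction of -6.93 ± 0.35 (SE, limma adjusted p = 1.5e-05), also limited by background, in the deleted embryoid bodies. ILMN_1256343 rose in the control line, from 2177 ± 223 (SD, n = 2) to 15966 units, and fell in the deleted line, from 2776 ± 513 (SD, n = 2) to 170.7 units. In the other direction ILMN_2645460 had an interaction of 3.94 ± 0.62 (SE, limma adjusted p = 0.0041). ILMN_2538597 had one of 3.66 ± 0.21 (SE, limma adjusted p = 3.0e-05), falling from 4797 to 726 units in the control line and rising from 4075 to 7676 units in the deleted line. The count depended on the stem cell arrays. It was 945 without control stem cell replicate 1 and 1356 without deleted stem cell replicate 1, and median scaling gave 1707, of which 892 were more positive and 815 more negative.

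Deleted and control stem cells were compared to ask whether expression differed before differentiation. With limma, 0 probes passed the threshold, and the smallest adjusted p was 0.51. At an unadjusted p under 0.05 there were 2091 probes, or 8.99%, against 5% by chance. The trended robust fit and the fit with array weights also gave 0 calls, with 2142 and 1669 probes at the unadjusted level. As no probe passed, none of the probes named above did, which says nothing about them in particular. Among them the largest log2 differences between stem cell groups were -1.18 ± 0.43 (SE) for ILMN_2860932 and -0.83 ± 0.30 (SE) for ILMN_2960700. With 2 arrays per group, changes of 1 on the log2 scale were recovered in 60% of simulated cases, all in brighter probes. Observed differences ran from -1.30 to 2.20 on the log2 scale without a call. Differences below 1, and also larger ones, may thus have gone undetected. The 2 deleted arrays were unlike each other. Their log2 difference across probes had an SD of 0.339, and 357 probes differed by at least 2-fold, against an SD of 0.263 and 116 probes between the control pair. The most similar pair of all 11 arrays was control replicate 2 and deleted replicate 2, at r = 0.995. Of the other 2 ways to pair the 4 stem cell arrays, one gave 1558 and the other 900 probes at the unadjusted level. Without deleted replicate 2 there were 501 calls and without control replicate 2 there were 42, while leaving out replicate 1 of either line gave 0. Across probes, the genotype differences in stem cells and in embryoid bodies, which share no arrays, correlated at Pearson r = -0.18 and Spearman rho = -0.20.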

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

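The test of whether probes raised in deleted stem cell replicate 1 follow the control line's stage change, its repeat against deleted replicate 2 alone and the simulated mixtures of control groups were chosen after the results were seen. The genotype difference differed between stages for 2693 probes by the interaction test. Among the named probes it did so at -7.11 for ILMN_1225816, -6.93 for ILMN_1256343, -4.61 for ILMN_2693895, -3.81 for ILMN_2708477, 2.24 for ILMN_2960700, 3.57 for ILMN_1249766, 3.66 for ILMN_2538597 and 3.94 for ILMN_2645460, all on the log2 scale. The sizes for ILMN_1225816, ILMN_1249766 and ILMN_1256343 are limited by array background. Those for ILMN_2693895 and ILMN_2708477, whose lowest group means were 229 and 209 units, are also compressed by it. Of 15 measures examined in the 4 deleted embryoid body arrays, 2 had an array far from the rest, where chance gives about 1 in 20. For ILMN_1225816 the gap over the range was 0.890, from replicate 1 at 126 units against 112 to 113, all undetected. For ILMN_1256343 it was 0.964, from replicate 2 at 255 units against 141 to 144.

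The number of probes that differed between deleted and control embryoid bodies exceeded what other assignments of the same arrays gave. Of the 35 splits of the 7 arrays into 3 and 4, 1 gave as many, the real one with 5246, and the highest other split gave 81. Every other split mixes arrays of the 2 lines, which adds any real difference to the spread and lowers its count. The 35 splits are also too few to exclude chance, and they cannot tell genotype from any other difference between the lines.

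Deleted embryoid bodies lay between control stem cells and control embryoid bodies. The tables argue against array normalization or background as the whole cause, since the ratio of deleted to control stage change, 0.430 as normalized, was at most 0.450 after median scaling or neqc. A simple mixture of undifferentiated cells with control-like embryoid body cells was tested by asking how many genotype calls lay past both control groups in the same direction. That held for 30.3% of the 5246 calls, against 0.208% on average in 20 simulated mixtures with a 56.0% share of control bodies. Any mixture of the 2 control means lies between them by construction, so the simulated value reflects noise alone, whatever the share. A mixture of the 2 control groups may thus contribute but is not the whole pattern. Mixtures with deleted stem cells were not simulated. The genotype, any other difference between the 2 cell lines, a delay in differentiation and a change in cell types within the bodies stay open, as untested.

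Deleted stem cell replicate 1 stood apart from the other stem cell arrays, with 416 probes at least 2-fold above their mean and 46 as far below, and control replicate 1 did so with 95 above and 183 below. For the deleted array, background is argued against, since it lay at 28.5% of the way to control embryoid bodies after neqc background correction. Of its raised probes, 69.5% rose in the control line's stage comparison, against 18.3% of all probes, and 61.0% of the 313 probes raised against deleted replicate 2 alone did so, a set chosen without control arrays. This is consistent with a share of cells further along the same change, as a hypothesis. Of the probes raised in the deleted array, 14.7% were at least 2-fold above both embryoid body groups, against 57.9% of the 95 raised in control replicate 1. This leaves open whether RNA of cells that the embryoid bodies lack, such as the feeder layer under the stem cells, is also present. Probes were not matched to feeder genes.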

How the results depend on the processing

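The alternatives that could be run left the embryoid body count within 1.5 times of 5246, at 4066 to 6047 including each array left out and the array weights chosen after seeing the data. Median scaling lowered the interaction count to 1707 and turned the balance of upward against downward calls in the 4 comparisons with calls, and the cause was not tested. The stem cell comparison stayed at 0 under each alternative scaling, filter and fit, and ranged from 0 to 501 with 1 array left out: 501 without deleted replicate 2 and 42 without control replicate 2. With 1 array left out, the control line's stage count ranged from 5232 to 9003, the deleted line's from 2627 to 5495 and the interaction's from 945 to 3392, lowest without control stem cell replicate 1, deleted stem cell replicate 2 and control stem cell replicate 1. In these fits a lone array is assumed to vary like the other groups. The ratio of stage changes ranged from 0.315 to 0.544. The position of deleted embryoid bodies stayed at 54.6% to 59.2%. The 16 named results kept their direction and side of the threshold in all 300 alternatives, but not their size. Because they were named for large changes past the threshold in these same arrays, this is not independent support for them. neqc, which removes background, moved the log2 fold change between embryoid bodies to -9.43 for ILMN_1225816, -8.04 for ILMN_1256343 and 5.05 for ILMN_1249766. It moved the control stage change to 9.38 for ILMN_1225816 and 7.56 for ILMN_2708477, and the deleted stage change to 3.93 for ILMN_2708477, 3.81 for ILMN_2670625, -7.37 for ILMN_2693895 and -7.55 for ILMN_2923445. The interaction became -9.52 for ILMN_1225816 and -8.40 for ILMN_1256343. Without control embryoid body replicate 3, the stage change of ILMN_1225816 was 7.89 and its interaction -7.96. Replicate numbers did not pair the samples, since deviations of same-numbered control and deleted embryoid bodies correlated at 0.077, -0.0087 and 0.188, and 0 of 3 control arrays correlated best with their own number. With the replicate block, counts were 4126 for embryoid bodies, 0 for stem cells, 7483 and 3556 for the stages and 1855 for the interaction. The gene list tests and the count with 1 probe per gene were not run, because probes were not matched to genes. No offset was added to the deposited intensities before the main log2 step, because no intensity was at or below 0.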

Other observations

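The share of calls outside both control groups was a test set before its result was seen, while the simulated mixtures were added after it. Deleted embryoid bodies held a set of transcripts outside the range of both control groups. Of the 5246 genotype calls, 873 probes were higher and 715 lower than in both control stem cells and control embryoid bodies, 30.3% in all. By at least 2-fold against each, 119 were higher and 71 lower, where simulated mixtures of the 2 control groups gave 1 at most. Such mixtures lie between the 2 control means by construction, so the simulated count reflects noise alone. Of the 14479 probes with no stage call in the control line, the interaction passed for 322 with a more positive and 218 with a more negative genotype difference in embryoid bodies. That is a smaller share than the 11.6% of all probes tested. An interaction call also does not place a probe outside both control groups. The 30.3% speaks against a plain mixture of the 2 control groups as the whole account. A delay through intermediate states with transcripts of their own, and a different make-up of cell types, were not tested and stay open. A difference in array run between stem cells and embryoid bodies, which no label gives, would also shift probes relative to control stem cells.

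Control embryoid body arrays were uneven at some of the named probes. ILMN_1225816 read 4811 units on replicate 3 against 25774 and 30517 on the others, ILMN_2693895 read 1102 against 5090 and 11654, ILMN_2645460 read 227 against 499.5 and 719, and ILMN_2923445 read 254 against 773 and 2562. ILMN_2708477 did not share this, at 25072 to 29624 units.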
